A study of Bos taurus with 18 samples.

How the data were processed

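Rumen papillae, the finger-like projections of the rumen lining, were sampled from 9 rumen-cannulated, non-lactating Holstein cows, of which 5 were controls and 4 received a supplement given in the labels only as PHY. Each cow was sampled on a diet of 100% forage and again on a high-grain diet with 65% concentrate. The labels do not expand PHY, and they do not say whether it was already fed at the time of the forage biopsy. The 18 RNA-seq libraries fell into 4 groups: forage_control (n = 5), forage_PHY (n = 4), grain_control (n = 5) and grain_PHY (n = 4). Replicate numbers follow the order of deposit. The labels tie no library to a cow, so the main model has no cow, and each diet comparison treats libraries of the same cows as independent. Total RNA was extracted with a column kit for small and large RNA, and libraries were made from 10 ng of it with a stranded total RNA kit (SMART-Seq Stranded), per the labels' protocols.

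The deposited table of counts holds whole-number read counts for 27270 Ensembl genes with a name beside each identifier. The deposited table of DESeq2-normalized signal holds the same counts divided by one size factor per library, which was checked on the values to a tolerance of 0.001, so all tests used the counts. Reads were demultiplexed with bcl2fastq 2.20, normalized with DESeq2 (version not stated) and assigned to the cattle build bosTau9, per the submitters' processing notes. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. Overlapping, antisense and near-identical genes could therefore share reads. The names of 7506 genes are only their Ensembl identifiers, and 279 genes had 0 reads in every library. The reference table at hand is of another assembly and pairs no Ensembl identifiers, so gene names are those of the deposited table and no coordinates are given.

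Differences between groups were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test with robust dispersion, after filterByExpr by group at its default minimums and TMM normalization. The model had 1 mean per group and no covariate, and all 18 libraries shared one estimate of the spread. After the filter 22202 genes were tested, with a biological coefficient of variation of 51.4%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. The 6 contrasts were grain against forage averaged over both arms, grain against forage in control cows, the same in PHY cows, PHY against control on forage, PHY against control on grain, and the difference between the diet responses of the arms. A fold change is given as log2 with its standard error (SE), and a level as CPM, the count scaled to library size, as mean ± SD over libraries. CPM of single genes was computed from edgeR's effective library sizes and CPM of the olfactory receptor genes and of the silent panel from total reads, and the log2 CPM used for principal components had a prior count of 2.

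Gene lists were tested with camera (limma 3.58.1) on voom values of the same model, two-sided, with a preset inter-gene correlation of 0.01, adjusted over the 35 lists of a contrast. The same test was run with the correlation estimated for each list, which no list passed in any contrast. List scores per library, means of log2 CPM with a pseudocount of 1 CPM, were compared by exact permutation, adjusted over the 35 lists. Unlike camera, this does not set a list against the other genes. The lists, the contrasts, the main test and the rule for named genes were fixed before the data were examined. The lists covered epithelial layers, junctions, cell division, lipid, ketone, energy and sugar metabolism, transport, immunity, stress, growth factors and the clock, markers of other cell types, and signs of RNA quality. The list of abundant non-coding RNAs has 16 symbols, but its 246 tested genes are mostly copies that share a symbol. For each contrast the rule named the 10 largest rises and the 10 largest falls among called genes with a symbol and a mean of at least 5 CPM in the higher group, up to 4 called members per list, and 19 preset genes whatever their test. Where no gene was called, it named the 3 smallest p in each direction. Only some of the list members that the rule allows are printed, as examples, and some genes the rule names are not reported here.

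Alternatives fixed beforehand were DESeq2's size factors in edgeR, no low-count filter, a stricter one, DESeq2 1.42.0, limma voom with sample quality weights, only the groups compared, a minimum absolute log2 fold change of 1, 1 surrogate variable (sva 3.50.0), an estimated correlation for lists, and leaving out each library in turn. Added after seeing the data were a background covariate (log2 CPM summed over 144 olfactory receptor genes, which most tissues do not express), leaving out the 3 libraries highest in that measure, a test of only the genes with a mean of at least 30 CPM, thinning every library to the lowest total, and the replicate number as a block. A panel of 60 other genes that are silent in most tissues served as a second background measure. Single values were compared with exact permutation tests, two-sided. Correlations with depth were tested by random shuffles of the libraries. The diet comparison over both arms exchanged libraries between diets within each arm. The pipeline was tested on simulated counts for 22202 genes with the real library sizes and no background. Over both arms it called 42 of 100 genes changed 2-fold and 84 of 100 changed 4-fold, with 10 false calls. The corresponding recoveries were 13 and 71 for the diet contrast in control cows, 10 and 61 in PHY cows, 17 and 71 for PHY on forage, 22 and 67 for PHY on grain, and 1 and 47 for the difference of responses. With the covariate, 16 and 66 were called over both arms without background, and 53 and 80 with the simulated background described next. The changed genes were drawn from those with a mean log2 CPM above 0. With a simulated background that followed the slopes of the real libraries, the model of groups alone gave 8074 false calls over both arms, 3872 in PHY cows and 9 in control cows, and camera called 21, 19 and 17 lists that had not been shifted. It called 4 such lists for PHY on forage, 13 for PHY on grain and 6 for the difference of responses. With the covariate the false calls were 12, 6 and 4, and the lists called 0 in each diet contrast, 1 for PHY on forage, 2 for PHY on grain and 0 for the difference. The simulated background was built from the same covariate that this model holds, and each gene was drawn independently. These low counts therefore cannot show that the covariate captures the real background, or that the preset correlation holds in real data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

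Library totals ran from 3953060 to 34471682 reads. The shallowest library therefore resolves a gene at 1 CPM with few reads, and intervals cover counting error only, since the reads carry no molecular identifiers that were used here. No library was set aside. The 32 pairs of libraries within groups all differed by more than sampling noise, with a lowest chi-square per degree of freedom of 16.6.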

Results

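RNA was measured in rumen papillae of 9 cows, sampled on forage and again on high grain, with 5 control cows and 4 PHY cows. Totals ran from 3953060 to 34471682 reads per library. They averaged 24120000 ± 7991000 reads (SD, n = 5) in forage_control and 26480000 ± 7931000 (n = 4) in forage_PHY. On grain they averaged 15650000 ± 7723000 (n = 5) in grain_control and 10630000 ± 4881000 (n = 4) in grain_PHY. Grain libraries held 0.47 times the reads of forage libraries over both arms (exact permutation p = 0.00374). In PHY cows the ratio was 0.371 (exact permutation p = 0.0286, the smallest this design allows). In control cows it was 0.595 (exact permutation p = 0.135). The most abundant gene, which has an identifier (ENSBTAG00000043570) and no symbol, took 20.7% to 43.8% of the reads of a library, and the next (ENSBTAG00000043567) took 7.84% to 19.7%.

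Reads on olfactory receptor genes moved with diet. The 144 genes together stood at 35.3 ± 21.0 CPM (n = 5) in forage_control and 24.2 ± 5.42 (n = 4) in forage_PHY. The values were 83.3 ± 60.3 (n = 5) in grain_control and 135.8 ± 140.7 (n = 4) in grain_PHY. They were 3-fold higher on grain over both arms (exact permutation p = 0.00227), 2.2-fold in control cows (p = 0.103, exact) and 4.08-fold in PHY cows (p = 0.0286, exact, the smallest possible). Between arms the ratios were 0.777 on forage (exact p = 0.452) and 1.44 on grain (exact p = 0.492). The panel of 60 other genes that are silent in most tissues was 3.44-fold higher on grain (exact permutation p = 0.00204), and the median gene 2.63-fold higher (exact permutation p = 0.00125). Across the 18 libraries log2 olfactory receptor CPM fell with log2 total reads (Pearson r = −0.94 and Spearman rho = −0.86). The random permutation p was 1e-05 for each, the smallest that the number of shuffles allows. Without the 2 libraries farthest from the median total, r was −0.86. Within forage libraries r was −0.78 (random permutation p = 0.012) and rho −0.73 (random permutation p = 0.032). Within grain libraries r was −0.93 (random permutation p = 0.00034) and rho −0.87 (random permutation p = 0.005). Without the 2 farthest libraries of each diet, r was −0.71 on forage and −0.76 on grain. Total reads are also the denominator of this CPM, so a fall with total reads is partly built in. The shuffles do not keep that link, so their p cannot separate it from a true dependence on depth. The olfactory receptor counts themselves ran from 424 reads (forage_PHY 4) to 1365 (grain_PHY 1). The 3 libraries with the highest olfactory receptor CPM were also the 3 with the fewest total reads. They were grain_PHY 1 at 345.3 CPM (3953060 reads), grain_control 1 at 168.6 CPM (5433497 reads) and grain_control 4 at 125.4 CPM (9944586 reads). The first principal component of all libraries held 55.9% of the variance and the next 5.16%.

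**Figure D1:**
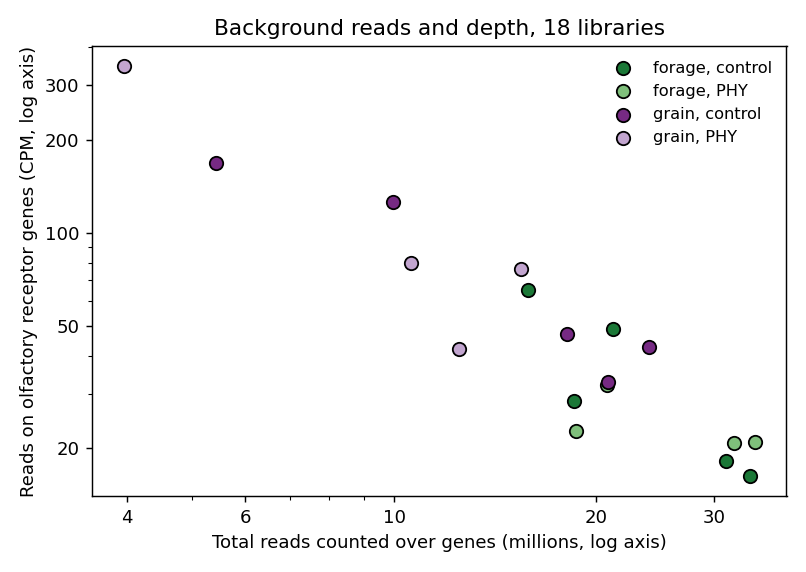
Summed CPM of 144 olfactory receptor genes (log axis) against total reads per library (log axis), 1 point per library, marked by group. The 3 libraries with the fewest reads, all on grain, have the highest values, from 125.4 to 345.3 CPM.

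The first question was how the papillae differed between the high-grain and the forage diet, over both arms. CYP1A1 and CYP1B1, enzymes that oxidise foreign compounds and are induced through the aryl hydrocarbon receptor, fell on grain. CYP1A1 (ENSBTAG00000001021) averaged 63.5 ± 47.4 CPM (SD, n = 9) on forage and 12.2 ± 5.85 CPM (n = 9) on grain. The log2 fold change was −2.31 ± 0.43 (SE), or 4.97-fold lower (edgeR adjusted p = 0.02). CYP1B1 went from 12.4 ± 6.06 to 5.33 ± 2.09 CPM (n = 9 each, log2 fold change −1.18 ± 0.25, edgeR adjusted p = 0.02). LYPD3, a surface protein of stratified epithelium, fell from 180 ± 54.3 to 85.9 ± 36.9 CPM. ZNF750, a regulator of keratinocyte differentiation, fell from 43 ± 15.1 to 19.4 ± 7.96 CPM. The largest rises were in genes of low level, such as the potassium channel KCNJ5, from 1.08 ± 0.891 to 5.26 ± 3.07 CPM.

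The edgeR test called 7091 of 22202 genes, 4023 higher and 3068 lower on grain. The smallest adjusted p was 0.011, and 11166 genes had an unadjusted p under 0.05. The median log2 change of all genes was 0.20 with TMM and 0.29 with DESeq2's size factors, which called 4302 higher and 2319 lower. Among genes of low mean level, under 0 on the log2 CPM scale, 919 rose and 2 fell, and among those over 6, 16 rose and 676 fell. The olfactory receptor reads moved with both directions. With their log2 CPM as a covariate edgeR called 0 genes (1032 at an unadjusted p under 0.05, smallest adjusted p 0.69). Without the 3 libraries highest in that measure it also called 0 (4265 unadjusted). All 3 are grain libraries, so fewer grain libraries were left, and this drop does not by itself point to background. DESeq2 called 9302 genes (6238 higher and 3064 lower) and limma voom with quality weights 10127, both without the covariate. Single libraries moved the edgeR count by over 1.5 times. It was 1 without grain_PHY 1, 2150 without forage_PHY 1 and 2860 without forage_PHY 2. It was 2890 without grain_control 1, 3544 without grain_control 4, 4278, 4489 and 4525 without forage_control 5, 4 and 1.

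The other large falls had log2 fold changes between −1.05 and −1.19. They were C10orf99 (−1.05 ± 0.32), ST6GALNAC2 (−1.06 ± 0.22), which sialylates O-linked sugars, CHCHD10 (−1.08 ± 0.27), a mitochondrial protein, and LYPD3 (−1.10 ± 0.24). The list went on with C18H19orf33 (−1.11 ± 0.30), COX8B (−1.15 ± 0.26), a cytochrome c oxidase subunit, bta-mir-2887-1 (−1.17 ± 0.36) and ZNF750 (−1.19 ± 0.24). The 10 largest rises among genes with a mean of at least 5 CPM in the higher group lay between 2.14 and 2.38, with KCNJ5 at 2.38 ± 0.49, the EPS8 relative EPS8L3 at 2.14 ± 0.45 and the folate enzyme ALDH1L1 at 2.24 ± 0.71. The glycosyltransferase GALNT14 was at 2.24 ± 0.44, the ephrin receptor EPHA8 at 2.23 ± 0.70 and the hepcidin regulator TMPRSS6 at 2.22 ± 0.45. IQCA1L (2.32 ± 0.58), ZNF541 (2.18 ± 0.49), CNBD2 (2.18 ± 0.44) and IGFN1 (2.15 ± 0.66) made up the rest. Their edgeR adjusted p ran from 0.02 to 0.03. With the olfactory receptor covariate CYP1A1 stood at −1.56 ± 0.57, CYP1B1 at −1.03 ± 0.38, LYPD3 at −0.32, ZNF750 at −0.36, KCNJ5 at 1.15 and EPHA8 at −0.07, none with an adjusted p under 0.05. No gene named in this paragraph passed without grain_PHY 1 (CYP1A1 −2.12, edgeR adjusted p = 0.062). Calls were also lost for C10orf99 without forage_PHY 1 or 2 (adjusted p = 0.056 and 0.052), ALDH1L1 without those or grain_control 1 (0.063, 0.057 and 0.061) and EPHA8 without forage_PHY 1 or grain_control 1 (0.063 and 0.057). They were lost for bta-mir-2887-1 without 2 of the libraries just named (0.056 and 0.052) and for IGFN1 without forage_PHY 1, forage_PHY 2 or grain_control 1 (0.058, 0.052 and 0.057).

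**Figure D2:**
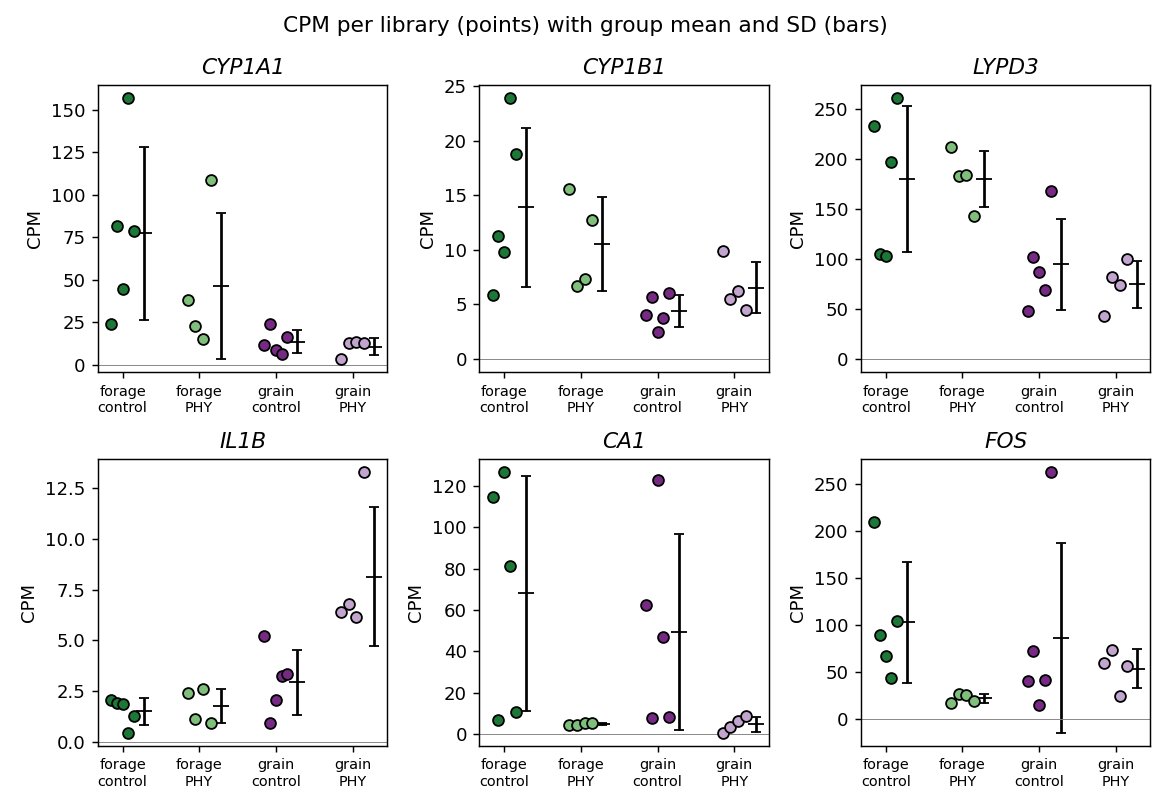
CPM of CYP1A1, CYP1B1, LYPD3, IL1B, CA1 and FOS in each library by group (linear axes), with group means and SD. CYP1A1 averages 77.3 CPM in forage_control and 13.4 in grain_control, and CA1 exceeds 40 CPM only in control libraries, 3 on each diet.

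Junction genes moved down on grain, and genes of the upper epithelial layers went both ways. Of 32 tested members of the junction list 18 fell and 1 rose (22 and 2 adjusted over the list alone), with a median log2 change of −0.61 (camera adjusted p = 2.2e-06; adjusted p = 0.41 with an estimated correlation). TJP3 (−0.72 ± 0.16) and CGN (−0.71 ± 0.18) of tight junctions fell, as did the adhesion protein NECTIN4 (−0.78 ± 0.18). The tight junction proteins CLDN1 (−0.88 ± 0.27), CLDN4 (−0.74 ± 0.24) and OCLN (−0.67 ± 0.20) fell too (edgeR adjusted p = 0.026, 0.029 and 0.025). Of 14 basal-layer genes 3 fell (5 adjusted over the list alone; median −0.49, camera adjusted p = 0.00013; adjusted p = 0.41 with an estimated correlation). The integrin ITGB4 (−0.72 ± 0.21) was among them. The keratin KRT5 was at −0.46 ± 0.27 (adjusted p = 0.17). Of 44 genes of the upper layers 14 rose, such as CRNN (1.64 ± 0.35) and the protease CASP14 (1.76 ± 0.49), and 8 fell (15 and 10 adjusted over the list alone). The median was 0.51 and the test had the opposite sign (camera adjusted p = 0.99). KRT10 was at −0.12 ± 0.26 (adjusted p = 0.70). Cell division genes shifted down slightly, 5 of 39 lower (0 adjusted over the list alone; median −0.24, camera adjusted p = 2e-04; adjusted p = 0.52 with an estimated correlation). The replication helicase subunit MCM5 was at −0.69 ± 0.20 and MKI67 at −0.47 ± 0.24 (adjusted p = 0.11). Adjusted for olfactory receptor reads, the medians were −0.01 for junctions, −0.02 for the basal layer, 0.17 for the upper layers and −0.01 for cell division. Without grain_PHY 1 none of these genes passed (smallest adjusted p 0.062, for TJP3). CLDN1 also failed without forage_PHY 1 or 2 (0.055 and 0.052), OCLN without forage_PHY 1 (0.052), and CLDN4 without forage_control 1, forage_PHY 1, forage_PHY 2, grain_control 1 or grain_control 4 (0.053 to 0.057).

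Many energy metabolism genes were lower on grain. Of 46 nuclear-encoded subunits of the respiratory chain and ATP synthase 40 fell (44 adjusted over the list alone), with a median of −0.67 (camera adjusted p = 1.5e-15; adjusted p = 0.41 with an estimated correlation). They included NDUFS7 (−0.93 ± 0.20), UQCRC1 (−0.81 ± 0.21) and ATP5F1D (−0.95 ± 0.23). The 13 mitochondrially encoded transcripts had a median of −0.55 with 0 called by edgeR and 0 adjusted over the list alone (camera adjusted p = 0.00043; adjusted p = 0.41 with an estimated correlation). Of 31 fatty acid oxidation and PPAR-responsive genes 14 fell and 3 rose (17 and 3 adjusted over the list alone; median −0.48, camera adjusted p = 0.00013; adjusted p = 0.41 with an estimated correlation). The nuclear receptor PPARD was at −0.90 ± 0.21 and the lipid droplet protein PLIN2 at −0.74 ± 0.21. Ketone body formation, for which the rumen epithelium uses butyrate, had 9 of 22 genes lower and 2 higher (12 and 2 adjusted over the list alone; median −0.49, camera adjusted p = 0.01; adjusted p = 0.41 with an estimated correlation). ACADS (−0.82 ± 0.25), which acts on short-chain acyl-CoA, fell. BDH1 was at −0.67 ± 0.24 (adjusted p = 0.041). Cholesterol synthesis had 8 of 24 lower (9 adjusted over the list alone; median −0.41, camera adjusted p = 4.8e-05; adjusted p = 0.41 with an estimated correlation). Its regulator SREBF2 was at −0.70 ± 0.19 and IDI1 at −0.82 ± 0.22. HMGCS1 was at −0.60 ± 0.28 (adjusted p = 0.089). In glycolysis 7 of 21 fell and 2 rose (10 and 2 adjusted over the list alone; median −0.40, camera adjusted p = 0.0016; adjusted p = 0.41 with an estimated correlation). With olfactory receptor reads as a covariate the medians were 0 for both respiratory lists, 0.01 for fatty acid oxidation, −0.02 for ketone formation, −0.01 for cholesterol and 0.08 for glycolysis. For the mitochondrially encoded transcripts the arms then went apart, at −0.29 in control cows (camera adjusted p = 2.9e-05) and 0.32 in PHY cows (0.0014; adjusted p = 0.71 and 0.81 with an estimated correlation). None of these genes passed without grain_PHY 1 (smallest adjusted p 0.062, for PPARD). BDH1 failed also without forage_control 4 or 5, any forage_PHY library, grain_control 1, 3 or 4 or grain_PHY 2 (0.055 to 0.072). HMGCS1 passed without forage_control 2 (−0.70, 0.033). ACADS was no longer called without forage_PHY 1 (−0.83).

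Transport genes went both ways. Of 57 acid, bicarbonate and ion transport genes 14 rose and 12 fell (15 and 13 adjusted over the list alone), with a median of 0.05 and a test of opposite sign (camera adjusted p = 0.73). The potassium channel KCNK5 (−0.81 ± 0.17), the sodium-proton exchanger SLC9A2 (−0.99 ± 0.21) and the anion transporter SLC4A9 (−0.60 ± 0.17) fell, and SLC26A9, an anion transporter, rose (1.65 ± 0.40). The monocarboxylate transporter SLC16A1 was at −0.41 ± 0.21 (edgeR adjusted p = 0.11), SLC9A3 at −0.33 ± 0.37 (0.46), SLC26A3 at −0.27 ± 0.40 (0.58) and carbonic anhydrase CA1 at −0.25 ± 0.66 (0.76). Of the IGF and EGF axis 8 of 27 fell (8 adjusted over the list alone; median −0.17, camera adjusted p = 0.025; adjusted p = 0.41 with an estimated correlation). The receptor ERBB2 (−0.71 ± 0.17) and the insulin receptor substrate IRS2 (−0.69 ± 0.20) were among them. IGFBP5 was at −0.59 ± 0.31 (adjusted p = 0.12). Clock genes shifted down, 8 of 17 (9 adjusted over the list alone; median −0.42, camera adjusted p = 0.00051; adjusted p = 0.41 with an estimated correlation). BHLHE40 was at −0.90 ± 0.22, NR1D1 at −0.81 ± 0.23 and DBP at −0.78 ± 0.20. With the olfactory receptor covariate the clock list kept a median of −0.20 (camera adjusted p = 0.0014; adjusted p = 0.37 with an estimated correlation). The IGF list was at 0.04 and the transport list at 0.04. Without grain_PHY 1 none of these genes passed (SLC9A2 −0.91, edgeR adjusted p = 0.062), and IRS2 also failed without forage_PHY 1 (0.051).

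Some inflammatory and immune cell genes were higher on grain. IL1B, the cytokine interleukin 1 beta, rose by a log2 fold change of 1.57 ± 0.35 (edgeR adjusted p = 0.02), and CXCL8, a chemokine that attracts neutrophils, by 1.60 ± 0.48 (adjusted p = 0.025), both from low levels. IL1A (1.02 ± 0.30) and the growth factor CSF3 (2.55 ± 0.77) rose as well, and TLR4 was at −0.52 ± 0.28 (adjusted p = 0.13). In the inflammation list 12 of 40 rose and 2 fell (12 and 2 adjusted over the list alone), with a median of 0.71 that camera did not call (adjusted p = 0.089; adjusted p = 0.41 with an estimated correlation). The score of this list per library was higher on grain (exact permutation p = 0.000113, the smallest possible, adjusted p = 0.00198). It was also higher in control and PHY cows alone (exact permutation p = 0.00794 and 0.0286, each the smallest possible, adjusted p = 0.0926 and 0.05). The score is not set against the other genes, and the median gene was itself 2.63-fold higher on grain. Over both arms the score of small nuclear RNAs was higher too (exact permutation adjusted p = 0.00397) and that of reference genes lower (0.0334). The score therefore does not single out inflammation. Of cell type markers, those of T and NK cells had 9 of 29 higher (11 adjusted over the list alone; median 0.80, camera adjusted p = 0.025; adjusted p = 0.55 with an estimated correlation). Those of B and plasma cells had 6 of 15 higher (10 adjusted over the list alone; median 1.33, adjusted p = 0.013; adjusted p = 0.41 with an estimated correlation). Myeloid markers had 8 of 21 higher (10 adjusted over the list alone; median 0.73, adjusted p = 0.021; adjusted p = 0.41 with an estimated correlation). Red blood cell markers had 4 of 9 higher (5 adjusted over the list alone; median 1.65, adjusted p = 0.028; adjusted p = 0.41 with an estimated correlation). CD8A was at 1.70 ± 0.46 and FLT3 at 1.74 ± 0.36. Adjusted for olfactory receptor reads, IL1B stood at 1.30 ± 0.40 and CXCL8 at 1.95 ± 0.52, both with an edgeR adjusted p of 1. The inflammation list then had a median of 0.33 (camera adjusted p = 0.0043; adjusted p = 0.37 with an estimated correlation), and the marker medians were −0.09 for T and NK cells, −0.02 for B cells, 0.27 for myeloid cells and 0.05 for red blood cells. Without grain_PHY 1 IL1B (1.64, edgeR adjusted p = 0.062), CXCL8 (1.73, 0.063) and the other genes of this paragraph lost their calls, and the inflammation list passed (0.79, camera adjusted p = 0.044). CXCL8 also failed without forage_PHY 1 or 2 (0.052 and 0.053), and IL1A without forage_PHY 1 or grain_control 1 (1.02 and 0.88). So did CSF3 without forage_PHY 1, grain_PHY 2 or grain_control 1 (2.35, 2.16 and 2.31), and the T and NK list without forage_control 5 (0.66, camera adjusted p = 0.059).

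Lists of stress and RNA quality moved as well, by camera with the preset correlation. Of 35 antioxidant genes 18 fell (20 adjusted over the list alone; median −0.59, camera adjusted p = 9.7e-07; adjusted p = 0.41 with an estimated correlation). The ferritin chain FTL was at −0.74 ± 0.20. Of 37 unfolded protein and heat shock genes 4 fell and 1 rose (0 adjusted over the list alone; median −0.29, camera adjusted p = 0.0016; adjusted p = 0.51 with an estimated correlation). The small heat shock protein HSPB1 was at −0.87 ± 0.25. Ribosomal protein genes had 46 of 75 lower (66 adjusted over the list alone; median −0.68, camera adjusted p = 3.4e-18; adjusted p = 0.41 with an estimated correlation), such as RPL28 at −0.92 ± 0.24. Reference genes had 2 of 14 lower (1 adjusted over the list alone; median −0.50, camera adjusted p = 0.00057; adjusted p = 0.41 with an estimated correlation). Small nuclear and other abundant non-coding RNAs had 58 of 246 higher and 1 lower (44 and 1 adjusted over the list alone; median 1.17, camera adjusted p = 9.8e-07; adjusted p = 0.41 with an estimated correlation). Matrix genes had 2 of 26 higher (0 adjusted over the list alone; median 0.04, camera adjusted p = 0.34). With olfactory receptor reads as a covariate the medians were 0.03 for antioxidant genes, 0.19 for unfolded protein genes (camera adjusted p = 1.1e-05; adjusted p = 0.49 with an estimated correlation) and 0.05 for ribosomal proteins. They were 0.17 for reference genes, 0.42 for non-coding RNAs and 0.79 for matrix genes (camera adjusted p = 7.8e-13; adjusted p = 0.49 with an estimated correlation). Without forage_control 5 the matrix list passed (0.31, camera adjusted p = 0.029), without forage_PHY 3 its median was −0.14, and FTL, HSPB1 and RPL28 lost their calls without grain_PHY 1 (edgeR adjusted p = 0.063 to 0.067). Over the 35 lists camera called 5 up and 15 down on grain with the preset correlation and 0 with an estimated one (smallest adjusted p 0.41). List scores per library differed between the diets for 26 of the 35 (exact permutation, adjusted p under 0.05), a test without the covariate.

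**Figure D3:**
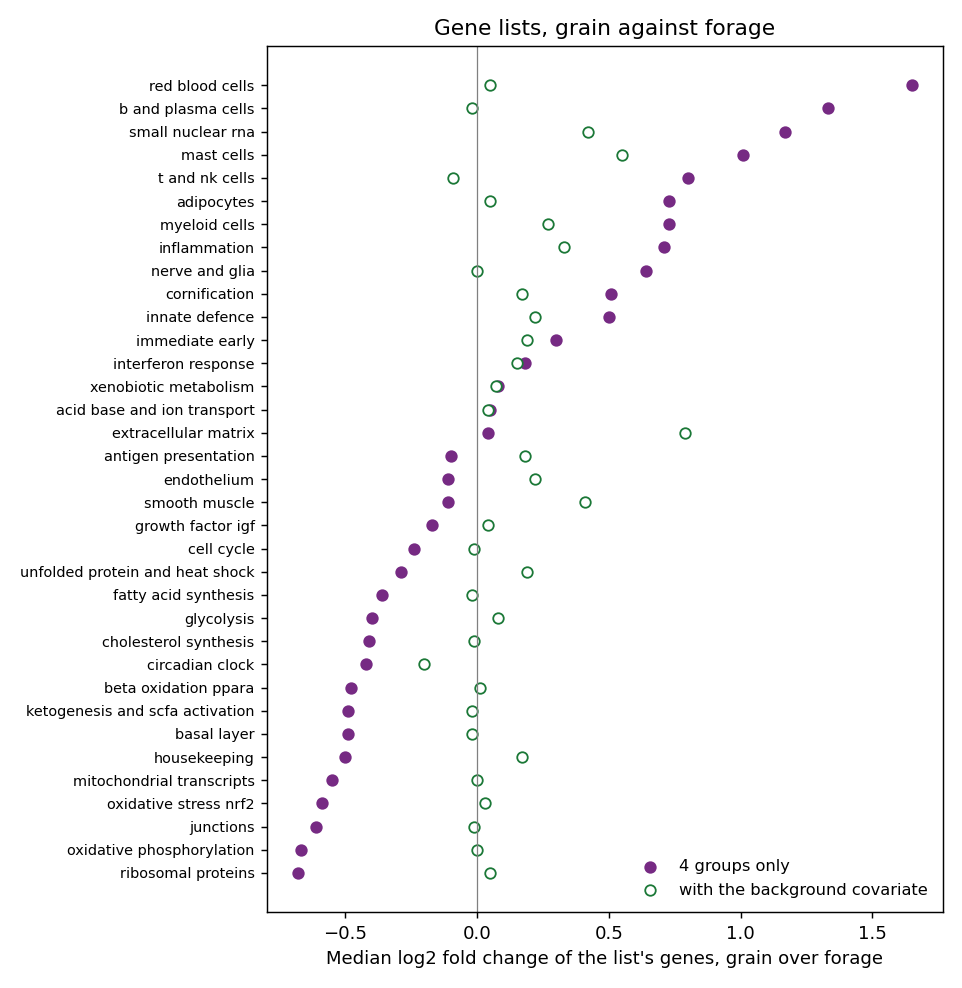
Median log2 fold change of grain against forage, over both arms, for each of the 35 gene lists (x axis), without and with the olfactory receptor covariate. The medians of respiratory chain and ribosomal protein genes, −0.67 and −0.68 without the covariate, lie at 0 and 0.05 with it.

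In control cows alone CYP1A1 and CYP1B1 were again among the genes with the smallest p, and no gene passed. CYP1B1 had a log2 fold change of −1.67 ± 0.34 and CYP1A1 of −2.52 ± 0.58, from 77.3 ± 50.8 CPM (n = 5) on forage to 13.4 ± 6.8 (n = 5) on grain, both at an edgeR adjusted p of 0.43. The lipase PNPLA2 was at −0.90 ± 0.22, and MYO1A (1.21 ± 0.30), the coagulation factor subunit F13A1 (1.18 ± 0.29) and MPP3 (1.57 ± 0.41) had the smallest p among higher genes, also at 0.43. Respiratory chain genes (median −0.48, camera adjusted p = 7e-13), ribosomal proteins (−0.45, 1e-16), junctions (−0.37, 9e-05) and the clock (−0.30, 0.00033) shifted down and B cell markers up (0.75, 0.005), each with an adjusted p = 0.52 with an estimated correlation. Adjusted over the list alone, 3 clock genes passed and 0 members of the other lists in this paragraph. edgeR called 0 genes (2518 at an unadjusted p under 0.05), DESeq2 0 (3479) and limma voom 0 (4637). Olfactory receptor reads were 2.2-fold higher on grain in these cows, and with them as a covariate edgeR called 0 genes (976 unadjusted). The medians were then 0.04 for the respiratory chain, 0.04 for ribosomal proteins, 0.05 for junctions and 0.07 for B cell markers (camera adjusted p = 0.56, 0.6, 0.97 and 0.43), and of these lists only the clock stayed called (−0.18, 0.0025; adjusted p = 0.32 with an estimated correlation).

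In PHY cows alone IL1B averaged 1.77 ± 0.854 CPM (n = 4) on forage and 8.14 ± 3.43 (n = 4) on grain, and all 4 grain values (6.13 to 13.3 CPM) lay above the highest forage value of 2.6 CPM. Its log2 fold change of 2.19 ± 0.53 did not pass (edgeR adjusted p = 0.07). CLDN1 was at 25.1 ± 8.6 and 8.46 ± 4.35 CPM (n = 4 each, −1.57 ± 0.41) and CYP1A1 at 46.4 ± 43 and 10.7 ± 4.88 CPM (−2.11 ± 0.64), both with an edgeR adjusted p of 0.07. The smallest p belonged to MEX3D (−1.21 ± 0.22), MINDY1 (−1.05 ± 0.21) and TMEM97 (−1.22 ± 0.27), lower on grain. Among higher genes SMIM6 and PHACTR1 (2.43 ± 0.53) were among those with the smallest p, and all 5 genes were at 0.07. SMIM6 had 0 reads in the 4 forage_PHY libraries and 0.903 ± 0.495 CPM (n = 4) in grain_PHY. Respiratory chain genes (median −0.83, camera adjusted p = 1.6e-15; adjusted p = 0.39 with an estimated correlation; 43 of 46 lower adjusted over the list alone) and junctions (−0.80, 7.7e-07; adjusted p = 0.39 with an estimated correlation; 20 lower and 1 higher adjusted over the list alone) shifted down. So did cell division (−0.43, 9.2e-06; adjusted p = 0.44 with an estimated correlation; 0 adjusted over the list alone) and ribosomal proteins (−0.89, 6.6e-17; adjusted p = 0.39 with an estimated correlation; 42 lower adjusted over the list alone). B cell markers shifted up (1.58, 0.028; adjusted p = 0.44 with an estimated correlation; 0 adjusted over the list alone). edgeR called 0 genes (8820 at an unadjusted p under 0.05, smallest adjusted p 0.07). DESeq2 called 5275 (3879 higher and 1396 lower), limma voom 7895 (4476 and 3419) and edgeR on these 8 libraries alone 4353 (3235 and 1118). Olfactory receptor reads were 4.08-fold higher on grain in these cows, and with them as a covariate edgeR called 0 genes (663 unadjusted) and the medians were −0.01, −0.05, −0.11, 0.06 and −0.06.

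The next question was whether PHY and control cows differed on forage. FOS and DUSP1, immediate early genes that respond within minutes to stimulation and to tissue handling, had lower means in PHY cows, and neither passed. FOS was at 103 ± 64.1 CPM (n = 5) in controls and 22.4 ± 4.79 (n = 4) in PHY cows, and DUSP1 at 35.8 ± 28.4 and 9.33 ± 1.85 CPM. CA1, a carbonic anhydrase, was at 68.2 ± 56.9 CPM (6.93 to 127) in controls and 4.86 ± 0.613 in PHY cows. Log2 fold changes were −2.20 ± 0.65 for FOS, −1.93 ± 0.53 for DUSP1 and −3.81 ± 1.04 for CA1. They were 1.11 ± 0.32 for AZGP1 and 2.10 ± 0.61 for ISG12(B), both higher in PHY cows. The edgeR adjusted p of each was 1. The olfactory receptor gene OR1B1 had 0 reads in the 5 forage_control libraries and 0.331 ± 0.235 CPM (n = 4) in forage_PHY.

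Cell division genes shifted up in PHY cows on forage (median 0.43, camera adjusted p = 9.8e-22; adjusted p = 0.53 with an estimated correlation), with 0 of 39 passing adjusted over the list alone, as did matrix genes (0.67, 3.7e-06; adjusted p = 0.85 with an estimated correlation; 0 adjusted over the list alone). Immediate early genes shifted down (−0.50, 1.3e-11; adjusted p = 0.30 with an estimated correlation; 2 lower adjusted over the list alone), and so did red blood cell markers (−0.65, 0.013; adjusted p = 0.85 with an estimated correlation), where the 1 gene lower adjusted over the list alone was CA1. With the olfactory receptor covariate the medians were 0.38, 0.52, −0.52 and −0.34. None of these lists passed by its score per library (exact permutation adjusted p = 0.878 each). edgeR called 0 genes (356 at an unadjusted p under 0.05), DESeq2 0 (596) and limma voom 0 (847). The matrix list was not called without forage_PHY 1 (0.37, camera adjusted p = 0.094) or forage_PHY 2 (0.35, 0.12), nor the red blood cell list without forage_control 3 (−0.73, 0.18), forage_PHY 1 (−0.48, 0.094) or forage_PHY 2 (−0.49, 0.11).

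On grain, no gene passed the test between PHY and control cows. AZGP1, a secreted lipid-mobilising glycoprotein, was at 4.35 ± 1.38 CPM (n = 5) in controls and 10.6 ± 2.81 (n = 4) in PHY cows (log2 fold change 1.30 ± 0.32). CA1 was at 49.5 ± 47.4 CPM (7.69 to 123) and 4.64 ± 3.52 (−3.39 ± 1.04), IL1B at 2.94 ± 1.6 and 8.14 ± 3.43 (1.48 ± 0.48) and CLDN1 at 16.7 ± 7.56 and 8.46 ± 4.35 (−0.99 ± 0.39). ERI3 (−0.91 ± 0.24) and DCBLD2 (−1.02 ± 0.27) were among the lower genes with the smallest p. ZFHX2 (0.83 ± 0.22) and RINL (1.22 ± 0.33) followed AZGP1 among higher ones, all with an edgeR adjusted p of 1. Ribosomal protein genes (median −0.48, camera adjusted p = 2e-12), junctions (−0.29, 0.00026), unfolded protein genes (−0.25, 0.00034) and immediate early genes (−0.34, 0.0048) shifted down, each with an adjusted p = 0.72 with an estimated correlation and 0 members adjusted over the list alone. edgeR called 0 genes (571 at an unadjusted p under 0.05), DESeq2 0 (813) and limma voom 0 (1185). Without grain_control 5 none of the 4 lists passed (ribosomal proteins −0.17 and junctions −0.16, camera adjusted p = 0.09 each; unfolded protein −0.07, 0.22; immediate early −0.04, 0.49), and neither did unfolded protein genes without grain_PHY 1 (−0.13, 0.32) or immediate early genes without grain_PHY 3 (−0.31, 0.14). Adjusted for olfactory receptor reads, the medians were −0.15, −0.12, −0.04 and −0.26. By their scores per library none of the 4 lists passed (exact permutation adjusted p = 0.814 each).

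The diet response was also compared between the arms. No gene differed past the threshold. CLDN1 was at −1.39 ± 0.54, a more negative response in PHY cows. ERI3 (−1.07 ± 0.33), TWSG1 (−1.13 ± 0.37) and MIS18A (−1.39 ± 0.45) had the smallest p among lower genes and IFITM10 (3.79 ± 1.23), ELFN1 (4.03 ± 1.36) and ZIC5 (4.23 ± 1.44) among higher ones, all with an edgeR adjusted p of 0.95. IL1B was at 1.24 ± 0.69 (0.95) and CYP1A1 at 0.41 ± 0.83 (0.96). Cell division (median −0.38, camera adjusted p = 5.7e-06), respiratory chain (−0.36, 7.4e-07), ribosomal protein (−0.42, 3.3e-05) and junction genes (−0.39, 0.00028) had a more negative response in PHY cows, and mast cell markers a more positive one (0.80, 0.015), each with an adjusted p = 0.67 with an estimated correlation and 0 members adjusted over the list alone. edgeR called 0 genes (442 at an unadjusted p under 0.05), DESeq2 0 (728) and limma voom 0 (861). Calls were lost for the respiratory chain without grain_PHY 1 (−0.15, camera adjusted p = 0.053), for mast cells without it (0.63, 0.061), and for ribosomal proteins without forage_control 3 (−0.28, 0.1), grain_control 5 (−0.11, 0.35) or grain_PHY 1 (−0.26, 0.079). With olfactory receptor reads as a covariate the medians were −0.23, −0.07, 0.01 and −0.09 for the 4 lists that were lower and 0.09 for mast cells. Mitochondrially encoded transcripts, at a median of 0.34 without it (camera adjusted p = 0.11), stood at 0.61 (9.7e-14; adjusted p = 0.89 with an estimated correlation).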

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

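Of the tests in this part, the counts over other splits of the libraries, the camera tests of the lists and leaving out each library in turn were set before their results were seen; the others were chosen afterwards. Among 19 measures, 76 groups of 4 or 5 libraries were searched for a library that stands apart, and 8 were found, where chance gives about 1 in 20. In forage_PHY, replicate 3 had 32.19 CPM of olfactory receptor reads against 20.82 to 22.73 in the others. In grain_PHY, replicate 1 had 345.3 CPM against 42.08 to 79.83, a median gene at 9.613 CPM against 1.683 to 2.831, and CYP1A1 at 3.36 CPM against 12.7 to 13.6. In the same group replicate 2 had a score of 117.6 on the component with 5.16% of the variance against −20.98 to −9.258, and replicate 4 had IL1B at 13.3 CPM against 6.13 to 6.77. FOS stood at 263 CPM in grain_control 5 against 15.6 to 72.5, and DUSP1 at 84.8 CPM in forage_control 1 against 14.4 to 34.

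The diet response of 14 lists differed between the arms by camera with the preset correlation, and none did with an estimated one (adjusted p = 0.67 each). The differences in median, PHY minus control, were −0.39 for junctions, −0.38 for cell division, −0.44 for cholesterol synthesis, −0.31 for fatty acid synthesis, −0.36 for the respiratory chain, −0.3 for glycolysis, −0.22 for antigen presentation, −0.37 for antioxidant genes, −0.27 for unfolded protein genes, −0.39 for matrix genes, 0.8 for mast cells, −0.42 for ribosomal proteins, 0.5 for small nuclear RNAs and −0.41 for reference genes. Only junctions and cell division were called after leaving out any 1 library. Without grain_PHY 1 the others, except cholesterol synthesis, ended at −0.19 (fatty acid synthesis), −0.15 (respiratory chain), −0.11 (glycolysis), −0.13 (antigen presentation), −0.21 (antioxidant), −0.16 (unfolded protein), −0.14 (matrix), 0.63 (mast cells), −0.26 (ribosomal proteins), 0.13 (small nuclear RNAs) and −0.28 (reference genes), none called. Without grain_control 5 calls were lost for fatty acid synthesis (−0.22), glycolysis (−0.18), antigen presentation (−0.18), antioxidant genes (−0.15), unfolded protein genes (−0.14), ribosomal proteins (−0.11), small nuclear RNAs (0.31) and reference genes (−0.19). Without forage_PHY 1 they were lost for cholesterol (−0.28), fatty acid synthesis (−0.17), glycolysis (−0.26), antigen presentation (−0.28), matrix (−0.22), small nuclear RNAs (0.4) and reference genes (−0.33), and without forage_control 2 for cholesterol (−0.32), fatty acid synthesis (−0.23), glycolysis (−0.21), unfolded protein genes (−0.21), matrix (−0.27), small nuclear RNAs (0.24) and reference genes (−0.29). Without grain_control 2 they were lost for cholesterol (−0.26), fatty acid synthesis (−0.19), matrix (−0.35) and reference genes (−0.3), and without forage_control 3 for ribosomal proteins (−0.28), matrix (−0.27), small nuclear RNAs (0.12) and reference genes (−0.3). Without forage_control 4 fatty acid synthesis (−0.22), matrix (−0.24) and small nuclear RNAs (0.51) lost theirs, and without grain_control 4 fatty acid synthesis (−0.3), matrix (−0.43) and small nuclear RNAs (0.44). Fatty acid synthesis was also lost without grain_PHY 2 (−0.3), and matrix without forage_PHY 2 (−0.16), forage_PHY 4 (−0.47), grain_control 1 (−0.46), grain_control 3 (−0.33) or grain_PHY 3 (−0.39).

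The first pattern is the 7091 genes called between grain and forage. With the olfactory receptor covariate their median change in the called direction went from 1.13 (interquartile range 0.61 to 1.77) to 0.18 (0.03 to 0.45), 16.1% of its size, and within groups 6986 genes rose and 6194 fell with that measure, so background reads over genes that are silent in most tissues may account for most of the pattern. Whether the pattern rests on 1 library is not decided. Without any 1 library the same genes kept at least 84.9% of that median change, a measure chosen after the data were seen. These genes were called with every library included, which by itself favours a kept change. Without grain_PHY 1, the library with the fewest reads, they kept 85.1% (0.96) although only 1 was called. Fewer reads as such are argued against: with every library thinned to 3953060 reads, 48.4% of the genes were called again in the same direction. An effect of the grain diet itself cannot be told apart from the background, because the background was higher on grain, and 51 genes were called among the 3111 abundant ones without the covariate and 0 with it. Forage was sampled first and grain second, so diet cannot be told apart from the order of sampling either.

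Other splits of the libraries into groups of the same sizes were counted as a check on chance. For the diet contrast over both arms, 1 of 100 splits, the real one, called as many genes (7091, highest other 1). The real split also had the largest difference in background (1.584 on the log2 scale), and its count was 1 without grain_PHY 1. The splits treat libraries of the same cows as independent. Such a count was thus rare among splits, but a chance fall of high-background libraries into the grain groups is not excluded by it. In the other 5 contrasts the real split called 0 genes, which every split reaches whatever the data (100 of 100 for the diet in control cows, 35 of 35 in PHY cows, and 100 of 100 each for PHY on forage, PHY on grain and the difference of responses), so the count tests nothing and chance is not excluded there. The highest counts of the other splits were 7616 in control cows, 0 in PHY cows, 776 for PHY on forage, 1 for PHY on grain and 5386 for the difference of responses. Calls came from 8 of the other splits in control cows, 2 for PHY on forage and 2 for the difference, and the large counts among them point to a structure of the samples other than the groups. The splits with large counts also had large differences in background. Those with 7616, 4983, 1677 and 1539 calls in control cows ranked 1, 2, 3 and 5 of 100 by that difference. The one with 776 ranked 2 and the one with 5386 ranked 2. The other control splits with calls (37, 5, 4 and 1) ranked 98, 71, 12 and 50. For PHY on forage and for the difference of responses, the split ranked 1 called 0 genes.

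The second pattern is the fall of CYP1A1 and CYP1B1 on grain. Whether dilution by background reads is its whole cause is not decided. With the covariate CYP1A1 went from −2.31 ± 0.43 to −1.56 ± 0.57 (95% interval −2.8 to −0.32), keeping 67.4%. CYP1B1 went from −1.18 ± 0.25 to −1.03 ± 0.38 (−1.83 to −0.22), keeping 86.9%. Genes of the level of CYP1A1 (4 to 6 on the log2 CPM scale) shifted by a median of −0.41. Those of the level of CYP1B1 (2 to 4) shifted by −0.12. CYP1A1 was a preset gene, but the pair was taken up after both falls were seen. The intervals are not adjusted for that choice, so they cannot decide against dilution. Both calls ended with the covariate, where no gene of 22202 passed. Their unadjusted p rose to 0.017 and 0.015, and with 1032 genes at an unadjusted p under 0.05 in place of 11166 the adjustment left each at 1. Lower activity of the aryl hydrocarbon receptor is a candidate explanation that stays open: 5 rows of its other targets (2 of AHRR, and TIPARP, CYP1A2 and NQO1) ran from −0.78 to 0.08 with the covariate, with a median of −0.39, an AHRR row, and an SE of 0.51. Without it CYP1A2 was called higher on grain (1.95 ± 0.72, edgeR adjusted p = 0.044) and both AHRR rows were positive (0.56 and 0.16), opposite to CYP1A1. Without grain_PHY 1 both CYP1A1 and CYP1B1 had an edgeR adjusted p of 0.062.

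The third pattern is CA1, which exceeded 40 CPM in 3 of 5 control libraries on each diet and in no PHY library. Red blood cells in the control biopsies, which would bring far more globin than CA1, are argued against, since HBB reached at most 1.93 CPM in any library. A difference between the cows of the arms that does not come from PHY could give the pattern and cannot be told apart from PHY here: CA1 differed on forage (exact permutation p = 0.048, smallest possible 0.0159) and missed the threshold on grain (p = 0.0556, exact), but the labels do not say whether PHY was already fed at the forage biopsy. The 2 diets share their cows, so they are not independent evidence. In edgeR CA1 did not pass on either diet (adjusted p = 1).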

How the results depend on the processing

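The labels tie no library to a cow, and replicate numbers follow the order of deposit, so the main tests have no pairing. Deviations from group means correlated at −0.52 to 0.64 between forage and grain libraries of the same number (1 of 9 pairs over 0.1). Of 2880 numberings, 2059 reach that sum (exact p = 0.71). Adjusted for background the values were 0.012 to 0.2 (4 of 9), a sum that 4 numberings reach (exact p = 0.0014). Among abundant genes, also adjusted, they were −0.33 to 0.65 (7 of 9, exact p = 0.0059). There control numbers 1, 2 and 4 correlated better with another number (0.2, 0.34 and 0.42). Control numbers 3 and 5 and every PHY number correlated best with their own. The adjusted values are a hint from the data, not the design, that numbers mark cows. With the number as a block edgeR called 5103 genes over both arms and 0 in control cows, in PHY cows and for the difference; with block and background covariate the counts were 1, 3, 0 and 0. These were ENSBTAG00000048835 (1.09 ± 0.15 over both arms and 1 ± 0.15 in control cows) and, in control cows, HSPA5 (0.9 ± 0.16) and ENSBTAG00000050565 (−1.12 ± 0.18), named after their values were seen. The block, the background covariate, leaving out 3 libraries, the abundant genes and the thinning were chosen after seeing the data. For grain against forage over both arms, DESeq2's size factors, both filters, DESeq2 and limma voom gave 6621, 6924, 6899, 9302 and 10127 genes. The count was 0 with 1 surrogate variable (1210 at an unadjusted p under 0.05 in edgeR), 0 with the background covariate (1032) and 0 without the 3 libraries of highest background (4265). It was 51 among abundant genes and 3868 after thinning, where 3429 were shared with the main 7091. With a minimum absolute log2 fold change of 1 it was 3708, of which 3674 were higher and only 34 lower. The test of abundant genes held only 3111 genes and rescaled the libraries on them, and otherwise the cause of these moves was not tested. Leaving out 1 library gave 1 (without grain_PHY 1) to 9587 (without grain_control 5), with counts moved by over 1.5 times without forage_control 1, 4 or 5 (4525, 4489 and 4278), forage_PHY 1 or 2 (2150 and 2860) and grain_control 1 or 4 (2890 and 3544). In PHY cows the diet count of 0 became 5275 with DESeq2, 7895 with limma voom and 4353 with only these 8 libraries. The other 4 contrasts gave 0 genes in every further alternative run for them and without any 1 library. Thinning was run only over both arms, abundant genes only for the diet contrasts, and leaving out 3 libraries not for PHY on forage.

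Of the 76 gene results over both arms printed in the text, a part of those the rule names, 63 lost the call with the covariate and kept their sign, 8 changed sign and 5 stayed on their side, and with the surrogate variable 65, 4 and 7. Reversed log2 changes with the covariate were EPHA8 −0.07, CLDN4 0, SLC16A1 0.1, SLC9A3 0.55, SLC26A3 0.45, KRT5 0.24, IGFBP5 0.04 and IGFN1 −0.1, and with the surrogate variable EPHA8 −0.03, SLC9A3 0.42, SLC26A3 0.32 and IGFBP5 0. SLC9A3 was also at 0.28 in limma voom and ranged from −0.45 to 0.15 (without forage_control 4) with 1 library left out. In PHY cows all 8 named genes passed with DESeq2 and with limma voom; no named gene of the other contrasts changed sides.

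All 20 list calls over both arms were lost with an estimated correlation. With the covariate 18 were lost, unfolded protein genes passed in the other direction and only the clock stayed called. List tests that turned with the covariate had medians of −0.02 (basal layer), 0.17 (upper layers), 0.08 (glycolysis), 0.04 (transport), 0.18 (antigen presentation), 0.03 (antioxidant), 0.19 (unfolded protein), 0.19 (immediate early), 0.41 (smooth muscle), 0.22 (endothelium), −0.09 (T and NK cells), 0 (nerve and glia) and 0.17 (reference genes), and elsewhere −0.06 for B cells in PHY cows and −0.07, 0.01 and −0.09 for the respiratory chain, ribosomal proteins and reference genes in the difference of responses. With the stricter filter the upper layers (0.53) and detoxification (0.12) turned, the IGF list was lost (−0.13) and mast cells passed (1.06). With 1 library left out, medians of lists whose test turned ranged from −0.14 to 0.31 for matrix, 0.3 to 0.58 for the upper layers, −0.01 to 0.21 for detoxification, 0.09 to 0.55 for immediate early genes and −0.29 to 0.07 for smooth muscle, all at adjusted p far above the threshold except the matrix list without forage_control 5. Depth limits low genes most: the shallowest library, grain_PHY 1, has 3953060 reads.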

Other observations

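Some members of groups that belong to other processes also moved with diet, though camera called none of these lists. Antimicrobial and pattern recognition genes had 12 of 41 members higher on grain and 2 lower (12 and 2 adjusted over the list alone; median log2 change 0.50, camera adjusted p = 0.43; list score, exact permutation adjusted p = 0.0124), led by the protease inhibitor SLPI (2.89 ± 0.84, edgeR adjusted p = 0.023) and the peptidoglycan-binding protein PGLYRP1 (2.02 ± 0.58, 0.023). Interferon-stimulated genes had 5 of 44 higher (0 adjusted over the list alone; median 0.18, camera adjusted p = 0.36; list score 0.0119), among them the antiviral enzyme OAS2 (1.52 ± 0.42), and antigen presentation genes 2 higher and 3 lower of 21 (1 and 3 adjusted over the list alone; median −0.10, camera adjusted p = 0.086; list score 0.208). Of 62 detoxification genes 14 rose and 8 fell (15 and 9 adjusted over the list alone; median 0.08 with a test of opposite sign, camera adjusted p = 0.89; list score 0.0905), with ALDH3A1 at 2.66 ± 0.62 beside the falls of CYP1A1 and CYP1B1. Fatty acid synthesis genes had 8 of 21 lower and 1 higher (9 and 3 adjusted over the list alone; median −0.36, camera adjusted p = 0.051; list score 0.0725), and immediate early genes 2 of 24 lower and 1 higher (1 lower adjusted over the list alone; median 0.30 with a test of opposite sign, camera adjusted p = 0.73; list score 0.623). With the olfactory receptor covariate the medians were 0.22, 0.15, 0.18, 0.07, −0.02 and 0.19. Without grain_PHY 1 SLPI, PGLYRP1, OAS2 and ALDH3A1 lost their calls (edgeR adjusted p = 0.063 to 0.074), as did SLPI and PGLYRP1 without forage_PHY 1 (0.052 and 0.051). The fatty acid list passed without any 1 of forage_control 2 or 4, forage_PHY 2, 3 or 4, grain_control 2 or 5 and grain_PHY 1, 3 or 4 (camera adjusted p = 0.03 to 0.045), and antigen presentation without forage_PHY 3 (0.034), grain_control 5 (0.047) or grain_PHY 4 (0.047).

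Some markers of further cell types were higher on grain, though camera called none of these lists. Mast cell markers had 4 of 7 higher (4 adjusted over the list alone; median 1.01, camera adjusted p = 0.051; list score, exact permutation adjusted p = 0.0128), such as CPA3 (2.03 ± 0.59, edgeR adjusted p = 0.023), nerve and glia markers 3 higher and 2 lower of 13 (6 and 2 adjusted over the list alone; median 0.64, camera adjusted p = 0.27; list score 0.0148), such as SOX10 (2.46 ± 0.67), and adipocyte markers 3 higher and 1 lower of 9 (5 and 2 adjusted over the list alone; median 0.73, camera adjusted p = 0.32; list score 0.024). Smooth muscle markers had 1 higher and 1 lower of 13 (1 and 1 adjusted over the list alone; median −0.11, camera adjusted p = 0.78; list score 0.924) and endothelial markers 1 higher of 17 (0 adjusted over the list alone; median −0.11, camera adjusted p = 0.43; list score 0.833). The erythroid enzyme ALAS2 rose by 1.65 ± 0.48 while the globin HBB reached at most 1.93 CPM. The medians with the covariate were 0.55 for mast cells, 0 for nerve and glia, 0.05 for adipocytes, 0.41 for smooth muscle and 0.22 for endothelium, and SOX10 stood at 0.14 and ALAS2 at 0.05. Without grain_PHY 1 CPA3, SOX10 and ALAS2 lost their calls (edgeR adjusted p = 0.066 to 0.068), CPA3 also without forage_PHY 2 (1.86) and ALAS2 without forage_PHY 1 (0.052). The mast cell list passed without any 1 library other than forage_control 1, 4 or 5 or grain_PHY 2 (medians 0.91 to 1.44).

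Few abundant genes were called when the test held only them. Among the 3111 genes with a mean of at least 30 CPM, edgeR called 51 between the diets, 30 higher and 21 lower (707 at an unadjusted p under 0.05), a test chosen after the data were seen. Of the 51, 33 were called in the same direction in the main test. Library sizes and TMM factors were recomputed on these genes alone, which takes out a shift they share. Their median log2 change was −0.01, against −0.54 in the main test for genes over 6 on the log2 CPM scale. CYP1A1 (−1.87, adjusted p = 0.047), COX8B (−0.69), LYPD3 (−0.62), ST6GALNAC2 (−0.58) and PPARD (−0.43) fell, and copies of U1, U3 and SNORA73, the histone gene H4C8 (0.83), the chaperone DNAJA1 (0.56) and the kinase ATM (0.48) rose. With the olfactory receptor covariate edgeR called 0 of them.

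A hypothesis of genes present in some cows and absent in others was tested, with its prediction set before the result. If such genes were fixed per cow, each would be on in equal numbers of libraries on both diets within each arm. The gap between libraries that have a gene and those that lack it was first set to at least 2.5 on the log2 scale, which gave 1 gene, a copy of U2 with equal numbers on both diets. It was then lowered to 1 after the gaps were seen, which gave 114. Of these, 92 had an odd number of libraries in an arm, which a gene fixed per cow cannot have, and 62 were on only in grain_control 1 and grain_PHY 1, the 2 libraries with the fewest reads. The data thus argue against the hypothesis for this set as a whole. Among the other 22 genes, 11 had equal numbers on both diets in each arm, where random placing gives 11.5 ± 2.3, so this count decides nothing for them. A test chosen afterwards asked whether the same replicate numbers, which follow the order of deposit, had the gene on both diets. They did for 9 of the 22, a count that 2 of the 2880 numberings of the grain libraries reach, the real one included (exact p = 0.00069). The 9 include the 4 genes with the largest gaps (1.88 to 3.04), U2, CA1, ENSBTAG00000047029 and BOLA-DQB. For these 9 a stable difference between cows stays a candidate explanation, if the numbers mark cows, which the labels do not say. AZGP1 was higher in PHY cows on both diets, at 8.99 ± 3.52 against 4.14 ± 1.66 CPM on forage and 10.6 ± 2.81 against 4.35 ± 1.38 on grain, and did not pass on either (edgeR adjusted p = 1).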
